A study of Mus musculus with 72 samples.

How the data were processed

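The deposited values are counts of reads per gene for each library, per the labels and file headers, and every value was a whole number. The file held 74 columns, of which 72 were matched to a sample through their names. The other 2 columns matched no sample in the labels and were not used here. It listed 23930 genes, and 27 gene names that a spreadsheet had turned into dates were restored from the amplicon names. The aligner, genome build and counting program are not given in the sources used here, so no coordinates were taken from the file. Where the text says that genes lie near each other, the positions came from the RefSeq annotation of GRCm38.p6.

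The labels describe mouse lung lacking Gprc5a, amplicon libraries made from RNA and read on a semiconductor sequencer. They give for each library the animal, the tissue and the time. Each time group of normal-appearing lung held 9 or 10 libraries, 1 per animal. The letters F and M stand in the animal names and are not defined by the labels. In the 36 libraries with the letter F, Xist, which is transcribed from the inactive X chromosome, lay at 656 to 6032 CPM (counts scaled by library size) and the Y-linked Ddx3y at no more than 0.0722 CPM. In the 36 with the letter M, Xist lay at no more than 1.36 CPM and Ddx3y at 72.4 to 166 CPM. The terms ADN and ADC in the tumor titles are not defined by the labels either, and they are used here only as titles. Pairs of tumor and normal lung were taken from the animal names. Across the 16 pairs, the correlation of a tumor with the normal lung of its own animal, after the group means were removed, ran from -0.0632 to 0.409 with a median of 0.226, and 11 of 16 were over 0.1. No duplicated library was found, as the smallest chi-square per gene between libraries of a group was 30.3, against about 1 for repeats of the same library.

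Genes were tested with edgeR 4.0.16 in R 4.3.3 (limma 3.58.1). Low counts were removed with filterByExpr, libraries were scaled by TMM, dispersions were estimated with estimateDisp, and quasi-likelihood F tests were run on robust fits. The Benjamini-Hochberg adjusted p of 0.05 was the threshold. The normal lungs entered 1 fit of 39 libraries over 4 time groups with 14907 genes tested and 35 residual degrees of freedom. For tumors, the counts of all tumors of an animal were summed and compared with its own normal lung in a fit with an animal block, which kept 16 animals and 15457 genes. The contrasts were the tumor effect at each time, its average over the 16 animals, and its difference between 7 months and the 2 earlier times. ADC-titled tumors were compared with ADN-titled tumors within the 2 animals that had both, over 14000 genes. Levels are given as CPM with TMM scaling, mean ± SD, and changes as log2 fold changes ± SE. A fold against a group without any count is only a bound, and no such fold is given.

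Gene lists, group assignments, tests and alternatives were fixed before the data were examined. The 32 lists were proliferation, p53 and DNA damage response, xenobiotic metabolism, Nrf2 antioxidant, MAPK output, interferon response, antigen presentation, inflammatory mediators, immune checkpoints, extracellular matrix, gastrointestinal differentiation, circadian clock, immediate early and heat shock, mitochondrially encoded and ribosomal quality, and markers of alveolar type 2, alveolar type 1, club and secretory airway, ciliated, endothelial, fibroblast and smooth muscle, macrophage, neutrophil, T and NK cell, B and plasma cell, lymphoid tissue chemokines, dendritic cell, mast cell and basophil, erythroid, cardiac and skeletal muscle, adipocyte, mesothelial and neuroendocrine cells. Each list was tested with camera at its preset correlation of 0.01 and again with the correlation estimated from the data. Members were also adjusted over the list alone. A fixed panel of 12 genes was followed in every main comparison, and the genes named beyond it were the 8 largest called rises and falls with a mean of at least 5 CPM (4 in the other comparisons), and up to 4 members with the smallest p of each list that passed camera or had at least 5 called members. Of the called genes chosen this way, those whose call hung on many single libraries are left out of the text. Of the genes chosen by these rules, 2 (1 of them in the panel) are not reported here.

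The alternatives fixed beforehand were other size factors, total counts alone, no filter, DESeq2 1.42.0, limma-voom, the animal letter as a covariate, fits of the groups compared alone, no replicate block, each tumor library on its own, and tumors without ADC titles. Added after the data were seen were fits without 5 normal lungs over 300 CPM of Myh6, a heart muscle myosin. So were fits without the 2 normal lungs of the fewest counts, 7459147 and 8940742, and without 2 tumors over 200 CPM of Foxj1, a ciliated cell regulator. Most fits that left out 1 library or animal at a time were also added then. Camera on the antigen presentation list without its 2 genes of separate levels was added then too. Fixed beforehand were the fits without 1 animal for tumors at end of exposure or 3 months, and those without 1 ADC-titled tumor. In a self-test, counts were simulated from the dispersions and library sizes of the data, with 100 genes changed 2-fold and 100 changed 4-fold. For normal lung each gene had 1 mean over all libraries, and for tumors the fitted means with animal effects were used. At end of exposure 71 of 100 changes of 2-fold and 96 of 100 of 4-fold were found, and in the average over 16 tumor animals 64 and 83. For the tumors at end of exposure, with 3 animals, 3 and 49 were found, and for the letter by time interaction 12 and 70. Among unchanged genes 2, 4, 2 and 2 were called, with each gene drawn on its own, so noise shared between genes did not enter.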

Results

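Lungs of mice that lack Gprc5a, a G protein-coupled receptor of the lung epithelium, were profiled before, at the end of and after exposure to the tobacco nitrosamine NNK. The 72 libraries came from 39 animals. Normal-appearing lung was taken from 10 animals at baseline, at 8 weeks of age, from 10 at end of exposure (16 weeks), from 9 at 3 months after exposure (28 weeks) and from 10 at 7 months (44 weeks). Tumors came from 16 of the same animals: 4 tumors of 3 animals at end of exposure, 6 of 4 animals at 3 months and 23 of 9 animals at 7 months. Libraries held 7459147 to 21822522 counts, with 15644 to 18645 genes detected. Gprc5a itself had 0 to 4 counts per library, at most 0.310 CPM, with 41 of 72 libraries at 0, and was not tested. No unexposed animals of the later ages were analysed here, so time since exposure, age and NNK could not be told apart, and the time groups share the same baseline lungs. The groups also differed in genes with separate levels by animal, described below. Lta4h, 1 of them, was on its high side in 0 of 10 lungs at baseline and 9 of 9 at 3 months. A difference between the animals of the groups, such as line or litter, thus could not be told apart from time either.

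By the end of exposure, genes of the p53 and DNA damage response stood higher in normal-appearing lung, led by Cdkn1a, which encodes the cell cycle inhibitor p21. Cdkn1a went from 36.3 ± 9.09 CPM at baseline to 161 CPM (n = 10 in each group, range 110 to 204 CPM at end of exposure), a log2 fold change of 2.14 ± 0.15 (edgeR adjusted p = 5.21e-13). Every library at end of exposure lay above the highest at baseline, at 48.5 CPM. Gdf15, a stress-induced cytokine, rose by 4.56 ± 0.44 (edgeR adjusted p = 1.39e-09), Eda2r, a p53-induced receptor of the tumor necrosis factor family, by 2.03 ± 0.18 (1.57e-10). Tnfrsf10b, a death receptor, rose by 1.21 ± 0.14 (edgeR adjusted p = 1.13e-07). Of the 22 tested members of this list 14 rose and 8 did not pass, and 16 rose when adjusted over the list alone (median 0.80, camera adjusted p = 1.92e-36, and adjusted p = 1.01e-09 with an estimated correlation). Trp53 itself, the gene of p53, stayed at 66.4 and 65.1 CPM (log2 fold change -0.04, edgeR adjusted p = 0.897).

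**Figure D1:**
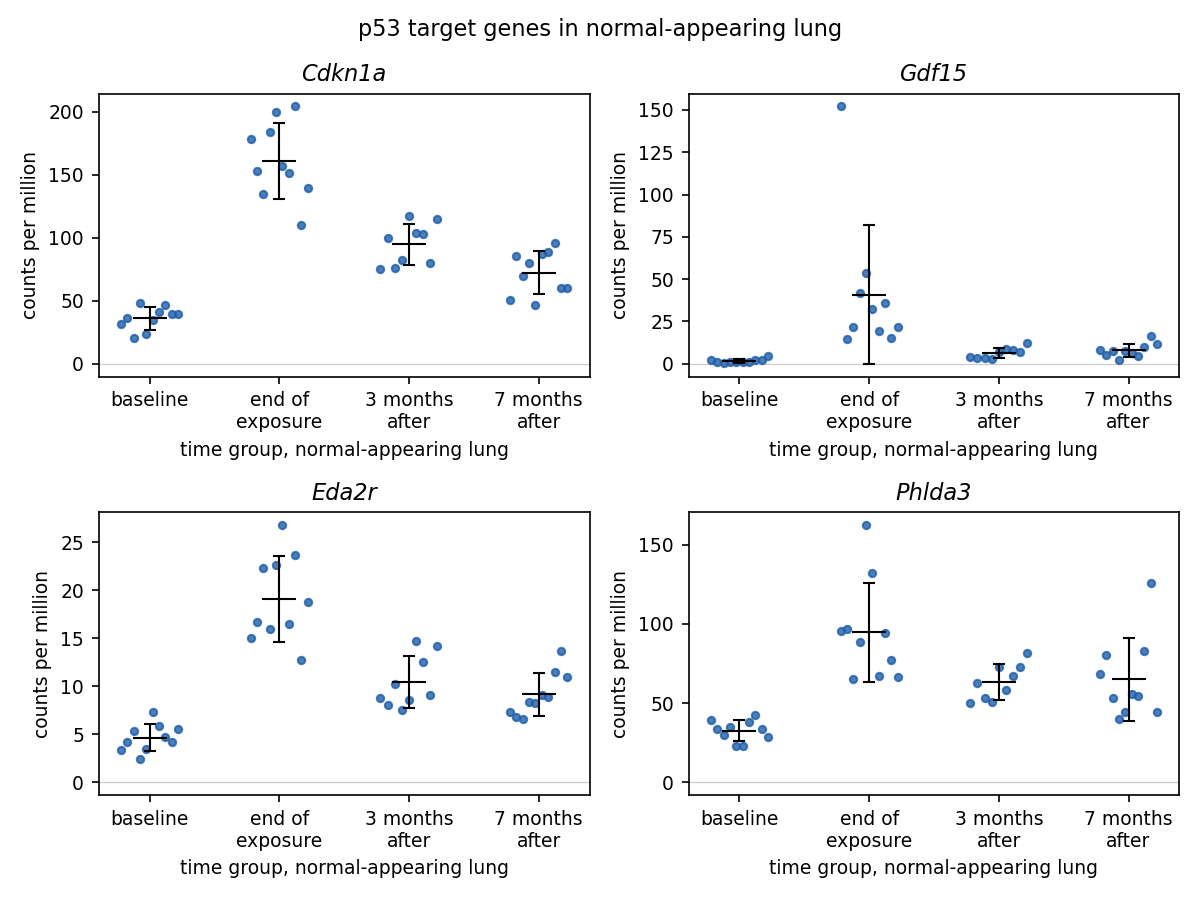
Levels in CPM of 4 p53 target genes in normal-appearing lung by time group, with 1 point per library and bars for mean ± SD. The 4 genes were highest at end of exposure, and at 3 and 7 months Cdkn1a stood at 94.9 ± 16.4 and 72.4 ± 17.3 CPM against 36.3 ± 9.09 CPM at baseline.

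Immune checkpoint genes and some interferon response genes were also higher at end of exposure. Ctla4, an inhibitory receptor of T cells, went from 1.54 to 8.91 ± 12.2 CPM (log2 fold change 2.53 ± 0.50, edgeR adjusted p = 0.00168). Pdcd1, the programmed death receptor, went from 1.75 ± 0.881 to 8.13 ± 7.98 CPM (2.21 ± 0.50, edgeR adjusted p = 0.00641). End-of-exposure replicate 4 stood apart with 42.3 CPM of Ctla4 and 27.0 CPM of Pdcd1. Without it the log2 fold changes were 1.74 (edgeR adjusted p = 0.0133) and 1.77 (0.0302). Foxp3, the transcription factor of regulatory T cells, rose by 2.39 ± 0.44 (edgeR adjusted p = 0.000551) and the costimulatory receptor Tnfrsf4 by 1.55 ± 0.26 (0.000171). Of the 15 immune checkpoint genes 9 rose and 6 did not pass, and 10 rose over the list alone (median 1.21, camera adjusted p = 3.36e-08, but adjusted p = 0.163 with an estimated correlation). In the interferon response 6 of 21 members rose, 11 over the list alone, among them Oasl1 by 1.52 ± 0.25 (edgeR adjusted p = 0.000102) and Irf7 by 0.95 (0.00794). That list had a median of 0.57 (camera adjusted p = 1.48e-07, and adjusted p = 0.163 with an estimated correlation). Cxcl9, a chemokine induced by interferon gamma, rose by 3.32 ± 0.54 (edgeR adjusted p = 0.000108). The 15 antigen presentation genes had a median of 0.50 (camera adjusted p = 0.000384, and adjusted p = 0.358 with an estimated correlation). EdgeR called 0 of them, with 7 under an unadjusted p of 0.05 and 0 called by DESeq2. Of 21 T and NK cell, 17 macrophage and 17 B and plasma cell genes, edgeR and DESeq2 called 0 at this time, with 1, 5 and 2 under an unadjusted p of 0.05 (camera adjusted p = 0.995, 0.443 and 0.0929).

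Proliferation genes stood slightly higher at end of exposure, with Cdk1, the mitotic kinase, up by 0.82 ± 0.19 (edgeR adjusted p = 0.00770) and Top2a, a topoisomerase of dividing cells, by 0.80 (0.0135). Of the 24 members 6 rose and 18 did not pass, 13 over the list alone (median 0.47, camera adjusted p = 3.36e-08, and adjusted p = 0.163 with an estimated correlation). Mki67 stood at 18.2 and 25.4 CPM (edgeR adjusted p = 0.288). In the MAPK output list 2 of 14 members rose and 12 did not, 3 over the list alone. Areg, a ligand of the epidermal growth factor receptor, rose by 2.21 ± 0.34 (edgeR adjusted p = 3.84e-05) and Etv4, an ETS factor downstream of ERK signaling, by 1.99 ± 0.34 (0.000158). The camera adjusted p of that list was 0.00328, and adjusted p = 0.163 with an estimated correlation. Hnf4a, a transcription factor of liver and gut, went from 0.128 to 3.00 CPM (edgeR adjusted p = 8.45e-07). It was the 1 called gene of the 8 in the gastrointestinal differentiation list (camera adjusted p = 0.0152, and adjusted p = 0.163 with an estimated correlation). Among the largest rises were Sectm1b at 4.19 ± 0.39 (edgeR adjusted p = 1.05e-09), Cd177, a neutrophil surface protein, at 4.04 ± 0.64 (8.96e-05), and Chil4, a chitinase-like protein, at 7.03 ± 1.58 (0.00617).

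Some genes of airway secretion and of chemical metabolism fell at end of exposure. Scgb1c1, a secretoglobin, fell from 180 ± 59.6 to 40.1 ± 19.2 CPM (log2 fold change -2.18 ± 0.30, edgeR adjusted p = 5.18e-06), and Chad, counted here among the airway secretory markers, fell by 2.04 (edgeR adjusted p = 0.00200). Of 15 club and secretory airway genes 3 fell, 4 over the list alone (median -0.43, camera adjusted p = 0.00604, and adjusted p = 0.546 with an estimated correlation). Scgb1a1, the major club cell secretoglobin, stood at 27360 ± 7878 and 38460 CPM (edgeR adjusted p = 0.558). Of 22 xenobiotic metabolism genes 3 fell, 4 over the list alone, such as the glutathione transferase Gstm2 by 1.05 (edgeR adjusted p = 0.00320). Their median was -0.34 (camera adjusted p = 0.00659, and adjusted p = 0.320 with an estimated correlation). Kdr, a receptor of vascular endothelial growth factor, fell by 0.79 ± 0.17 (edgeR adjusted p = 0.00382) as the 1 called gene of 18 endothelial genes (camera adjusted p = 0.0233, and adjusted p = 0.736 with an estimated correlation). In the list for mitochondrially encoded and ribosomal quality, 2 of 3 tested members fell (1 with total counts), such as the ribosomal protein gene Rps3 by 0.61 (edgeR adjusted p = 0.0214; median -0.45, camera adjusted p = 0.0262, and adjusted p = 0.169 with an estimated correlation). Asgr1 fell by 2.32 ± 0.47 (edgeR adjusted p = 0.00188), Rasd1 by 1.49 ± 0.29 (0.00143), Lrrc26 by 1.48 (0.00318) and Lypd2 by 1.77 (0.0107).

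Lcn2, the iron-scavenging lipocalin, stood at 40.9 ± 12.1 CPM at baseline and 90.9 ± 68.5 CPM at end of exposure (log2 fold change 1.14 ± 0.33, edgeR adjusted p = 0.0349). That call was lost without end-of-exposure replicate 4 (0.79, adjusted p = 0.152), replicate 1 (0.0604) or replicate 3 (0.0606), and without baseline replicate 2 (0.0595), 5 (0.0700) or 10 (0.0613). The rise of the chemokine Ccl20, 2.95 ± 0.68 (edgeR adjusted p = 0.00771), was lost without end-of-exposure replicate 4 (1.45, adjusted p = 0.125). That of Alb, the gene of albumin, 3.26 (edgeR adjusted p = 0.0196), was lost without replicate 6 (0.47, adjusted p = 0.715). The fall of the brown fat gene Ucp1, -5.08 (edgeR adjusted p = 0.0195), was lost without baseline replicate 1 (-0.20, adjusted p = 0.938). That of Entpd8, -1.49 (edgeR adjusted p = 0.0132), was lost without baseline replicate 5 (-1.19, adjusted p = 0.0579). The inflammatory mediator list, to which Lcn2 and Ccl20 belong, had 2 of 17 members up, 4 over the list alone (camera adjusted p = 0.0233, and adjusted p = 0.538 with an estimated correlation). In all, edgeR called 612 of 14907 genes, 372 up and 240 down, of which 232 and 67 by at least 2-fold. Without the 5 normal lungs over 300 CPM of Myh6, a heart muscle myosin, 349 genes were called, and with only the 2 groups in the fit 1063. Of the 32 lists, 12 passed camera, 8 up and 4 down, and 1 with an estimated correlation.

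At 3 months after exposure some p53 targets were still above baseline, and Lcn2, Spp1 and Gpnmb stood higher. Cdkn1a, at 94.9 ± 16.4 CPM (n = 9), was up by 1.38 ± 0.15 (edgeR adjusted p = 3.54e-07), and Eda2r by 1.16 ± 0.18 (0.000118). Gdf15 rose by 1.85 ± 0.41 (edgeR adjusted p = 0.00919) and Phlda3, a p53-induced inhibitor of Akt, by 0.95 (0.00193). Of the 22 p53 list members 5 rose and 17 did not pass, 7 over the list alone (median 0.30, camera adjusted p = 1.15e-09, and adjusted p = 0.000564 with an estimated correlation). Lcn2, at 133 ± 77.6 CPM, rose by 1.69 ± 0.34 (edgeR adjusted p = 0.00282). Spp1, the gene of osteopontin, rose from 14.3 to 141 ± 140 CPM (3.30 ± 0.61, edgeR adjusted p = 0.00164). Gpnmb, a glycoprotein of lipid-laden macrophages, rose from 2.60 to 10.4 CPM (0.000500).

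Several immune lists were up at 3 months with few members called. In the macrophage list 2 of 17 rose, and over the list alone 7 rose and 1 fell (median 0.52, camera adjusted p = 1.12e-05, and adjusted p = 0.156 with an estimated correlation). Inflammatory mediators had 1 of 17 up, 4 over the list alone (median 0.80, camera adjusted p = 5.48e-07, and adjusted p = 0.0921 with an estimated correlation). Antigen presentation had 2 of 15 up, 3 over the list alone, with the class I gene H2-K1 up by 1.04 (edgeR adjusted p = 0.0114). The antigen presentation list had a camera adjusted p of 1.79e-07, and adjusted p = 0.156 with an estimated correlation. Its members H2-Aa and H2-Eb1 had separate levels by animal, described below, with 2 of 10 lungs on the high side at baseline and 9 of 9 at 3 months. Without these 2 genes the camera adjusted p was 1.12e-05, and adjusted p = 0.236 with an estimated correlation, and the median went from 0.51 to 0.39. Other H2 genes stayed in the list, and H2-Ob, outside it, was on its high side in the same numbers of lungs. Leaving out 2 genes thus need not remove a difference between animals. Of 17 B and plasma cell genes 1 rose, Jchain, the joining chain of polymeric antibodies, by 2.14 ± 0.47 (edgeR adjusted p = 0.00847). For B and plasma cell genes the median was 0.72 and the camera adjusted p was 2.93e-06, and adjusted p = 0.308 with an estimated correlation. Checkpoint genes had 1 of 15 up, 5 over the list alone (median 0.54, camera adjusted p = 4.75e-05, and adjusted p = 0.236 with an estimated correlation). The called one was Pdcd1lg2, a ligand of the programmed death receptor, at 2.47 ± 0.58 (edgeR adjusted p = 0.0143), and it was lost without 3-month replicate 9 (1.13, adjusted p = 0.239), by limma-voom (1.60, adjusted p = 0.128) and without the 5 lungs over 300 CPM of Myh6 (2.38, adjusted p = 0.0706). Pdcd1 and Ctla4 stood at 3.90 and 3.83 CPM (edgeR adjusted p = 0.331 and 0.221). The interferon response had 1 of 21 up, Oasl1 (edgeR adjusted p = 0.0236). Camera placed the interferon response list up (adjusted p = 0.00174, and adjusted p = 0.392 with an estimated correlation). Camera also placed the neutrophil list up (adjusted p = 0.00281, and adjusted p = 0.352 with an estimated correlation) and the T and NK cell list (adjusted p = 0.0385, and adjusted p = 0.692 with an estimated correlation). EdgeR called 0 members of either, with 2 and 3 under an unadjusted p of 0.05 and 0 by DESeq2.

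Of the structural and epithelial lists at 3 months, alveolar type 1 genes were up (median 0.38, camera adjusted p = 0.000325, and adjusted p = 0.352 with an estimated correlation). Igfbp2, a binding protein of insulin-like growth factors, at 1.19 ± 0.25 (edgeR adjusted p = 0.00699), was the 1 called gene of 14. Areg, at 1.53 ± 0.34 (edgeR adjusted p = 0.00908), was the 1 called gene of 14 in MAPK output (camera adjusted p = 0.0172, and adjusted p = 0.236 with an estimated correlation). The chitinase Chia1 rose by 0.90 (edgeR adjusted p = 0.0198) as the 1 of 17 alveolar type 2 genes (camera adjusted p = 0.0347, and adjusted p = 0.560 with an estimated correlation). The endothelial list was up (1 of 18 called, median 0.57, camera adjusted p = 0.000134, and adjusted p = 0.392 with an estimated correlation). So was the erythroid list (1 of 4, median 1.42, camera adjusted p = 0.000162, and adjusted p = 0.184 with an estimated correlation). Vwf, the von Willebrand factor, was the called endothelial gene at 1.17 (edgeR adjusted p = 0.0232), and lost its call by limma-voom (adjusted p = 0.0745) and without 3-month replicate 2 (0.0600), 4 (0.0513) or 5 (0.0779) or baseline replicate 10 (0.0503). Xenobiotic metabolism was down (2 of 22 fell, 5 over the list alone, camera adjusted p = 0.00106, and adjusted p = 0.236 with an estimated correlation). Extracellular matrix was down too (1 of 20, camera adjusted p = 0.00812, and adjusted p = 0.461 with an estimated correlation), with Col1a1 at -0.88 ± 0.22 (edgeR adjusted p = 0.0198, and 0.0506 without 3-month replicate 3). Without the 5 lungs over 300 CPM of Myh6, the calls of Areg (1.02, adjusted p = 0.185), Chia1 (0.63, adjusted p = 0.210) and Col1a1 (-0.70, adjusted p = 0.185) were lost. The club and secretory airway list had a median of -0.64 (camera adjusted p = 0.000134, and adjusted p = 0.308 with an estimated correlation). There edgeR called 0 of 15 genes, 6 had an unadjusted p under 0.05 and DESeq2 called 2. The adipocyte list had a median of -1.15 (camera adjusted p = 0.0275, and adjusted p = 0.544 with an estimated correlation), with 0 of 8 members called by edgeR, 2 under an unadjusted p of 0.05 and 1 by DESeq2.

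Among the largest single changes at 3 months, the protease inhibitor Spink5 rose by 2.89 ± 0.42 (edgeR adjusted p = 9.60e-05), Cd177 by 3.65 ± 0.64 (0.000988) and Tmem2, a cell surface hyaluronidase, by 3.51 ± 0.83 (0.0174). H2-Q1 fell by 2.26 ± 0.37 (edgeR adjusted p = 0.000390) and Slc37a1 by 1.86 ± 0.36 (0.00201). Whether H2-Q1 follows H2-Aa by animal was not tested. Asgr1 fell by 2.07 ± 0.48 (edgeR adjusted p = 0.0137) and the dynein gene Dnah8 by 1.47 ± 0.34 (0.0137). The fall of the P450 gene Cyp4f15, -1.34 (edgeR adjusted p = 0.0173), was lost without baseline replicate 5 (-1.16, adjusted p = 0.0528). Trp53, Cdkn2a, Sftpc, Scgb1a1, Mki67 and Cd274 were not called at 3 months. EdgeR called 257 genes, 162 up and 95 down, of which 113 and 49 by at least 2-fold, and DESeq2 called 433. Of the lists 18 passed camera, 14 up and 4 down, and 1 with an estimated correlation.

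At 7 months the normal-appearing lung held higher levels of inflammatory, neutrophil, macrophage and alveolar type 2 genes and lower levels of club cell, matrix and metabolism genes. Lcn2 reached 192 ± 95.1 CPM (n = 10), up by 2.22 ± 0.34 (edgeR adjusted p = 3.31e-05). Of 17 inflammatory mediators 12 rose and 5 did not pass, 14 over the list alone. Ccl3, a macrophage chemokine, rose by 2.02 ± 0.39 (edgeR adjusted p = 0.000705), the cytokine gene Il1b by 1.58 ± 0.32 (0.00101) and Cxcl5, a neutrophil attractant, by 3.64 ± 0.85 (0.00420). The list median was 1.47 (camera adjusted p = 1.88e-08, and adjusted p = 0.0647 with an estimated correlation). Of 11 neutrophil genes 10 rose, with S100a9, a calcium-binding protein of neutrophils, at 2.38 ± 0.53 (edgeR adjusted p = 0.00280), from 18.3 ± 9.90 to 95.7 ± 88.5 CPM, and Retnlg at 1.81 (0.00116). The neutrophil list had a median of 1.74 and a camera adjusted p of 1.04e-06, and adjusted p = 0.128 with an estimated correlation. Erythroid genes, given below, rose too, with a median of 2.22. Of 17 macrophage genes 8 rose, and over the list alone 8 rose and 1 fell. Gpnmb rose by 2.50 ± 0.34 (edgeR adjusted p = 6.05e-06), Marco, a scavenger receptor of alveolar macrophages, by 2.45 ± 0.42 (0.000162) and the integrin Itgax by 1.09 (0.000752). Camera gave the list an adjusted p of 5.95e-05, and adjusted p = 0.130 with an estimated correlation.

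**Figure D2:**
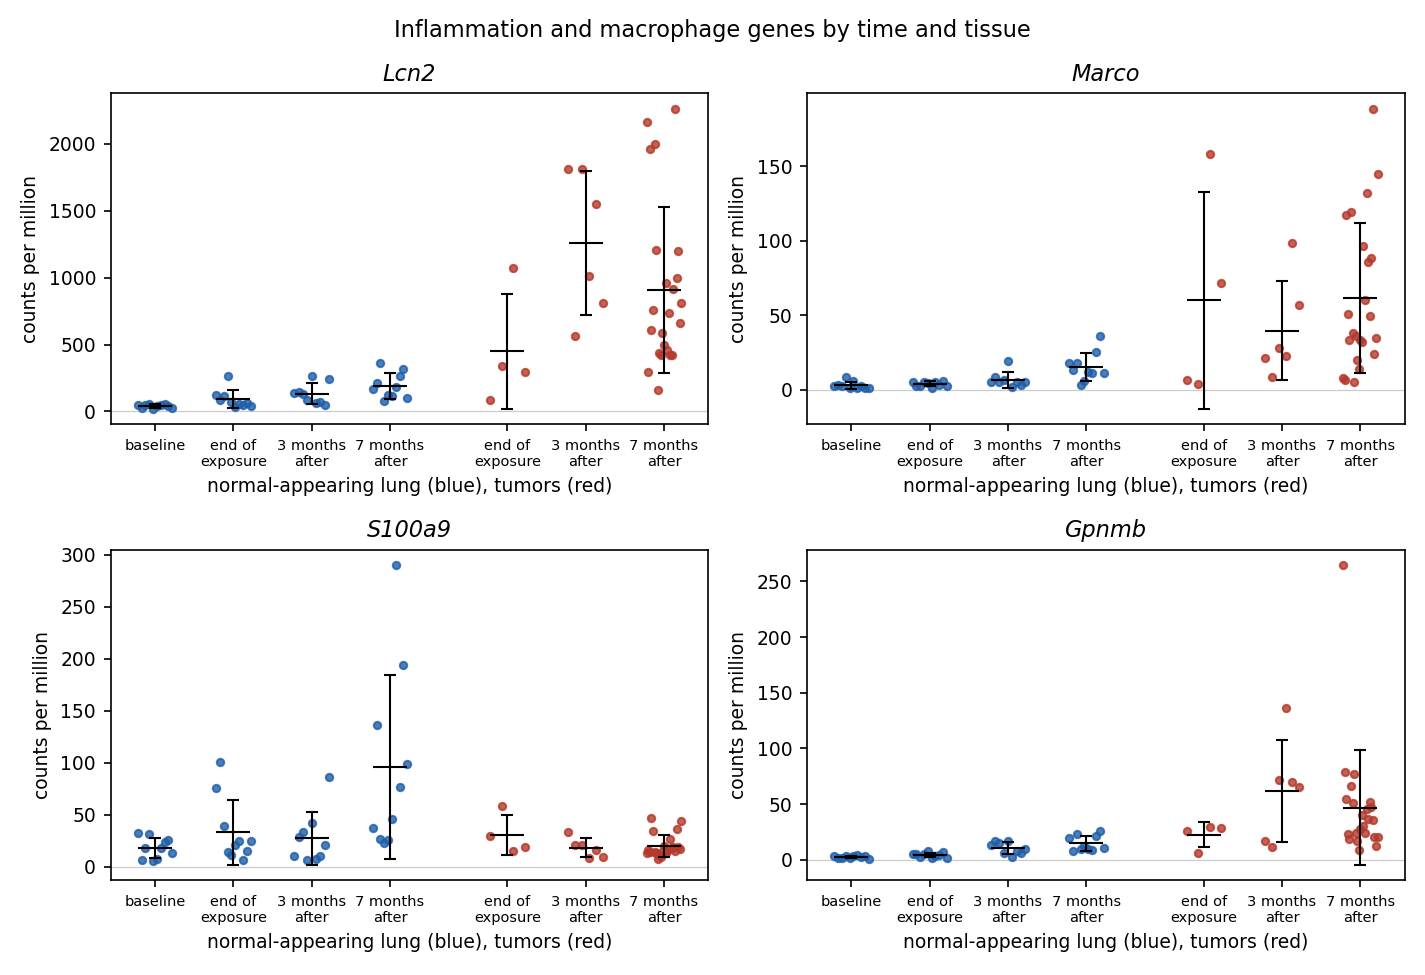
Levels in CPM of 4 inflammation and macrophage genes in normal-appearing lung (blue) and tumors (red) by time, with 1 point per library and bars for mean ± SD. Lcn2 stood at 40.9 ± 12.1, 90.9 ± 68.5, 133 ± 77.6 and 192 ± 95.1 CPM in the 4 normal groups and at 910 ± 620 CPM in tumors at 7 months.

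Epithelial genes moved in both directions at 7 months. Of 17 alveolar type 2 genes 9 rose (5 with total counts), and over the list alone 13 rose and 1 fell. Hc, complement component 5, rose by 1.41 ± 0.25 (edgeR adjusted p = 0.000218), the chemokine Cxcl15 by 1.43 (0.00264), the lysozyme gene Lyz2 by 1.28 (0.00376) and the phosphate transporter Slc34a2 by 0.91 (0.0172, and 0.0862 without the Myh6-high lungs). The camera adjusted p was 1.19e-05, and adjusted p = 0.260 with an estimated correlation. Sftpc, the surfactant protein C gene, stood at 7966 ± 4714 CPM against 4675 CPM (0.76 ± 0.29, edgeR adjusted p = 0.0731). It was called without 7-month replicate 4 (0.86, adjusted p = 0.0324), 6 (0.85, 0.0461) or 10 (0.88, 0.0397). Mfsd2a, a lipid transporter, rose from 3.62 ± 1.27 to 53.1 ± 39.2 CPM (3.87 ± 0.46, edgeR adjusted p = 6.41e-07), and Spink5 by 4.03 ± 0.44 (1.01e-07). Alveolar type 1 genes had 3 of 14 up (1 with total counts), 4 over the list alone, such as Igfbp2 at 1.26 (edgeR adjusted p = 0.000901). For alveolar type 1 genes the camera adjusted p was 0.00117, and adjusted p = 0.364 with an estimated correlation. Of 15 club and secretory airway genes 7 fell, 9 over the list alone. Cyp2f2, a P450 of club cells, went from 12530 ± 4173 to 4510 ± 2983 CPM (-1.48 ± 0.32, edgeR adjusted p = 0.00182). Camera placed the club and secretory airway list down (adjusted p = 0.000107, median -1.20, and adjusted p = 0.271 with an estimated correlation). Of 22 xenobiotic metabolism genes 10 fell, 12 over the list alone, such as the glutathione transferase Gsta3 at -1.47 ± 0.23 (edgeR adjusted p = 4.56e-05). The xenobiotic metabolism list had a camera adjusted p of 9.79e-06, and adjusted p = 0.128 with an estimated correlation.

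Matrix genes were lower at 7 months. Col1a1, a fibrillar collagen, went from 424 ± 134 to 185 ± 60.6 CPM (-1.20 ± 0.21, edgeR adjusted p = 0.000213) and Col3a1 fell by 1.18 ± 0.24 (0.000992). Of 20 matrix genes 7 fell and 13 did not pass (camera adjusted p = 5.95e-05, and adjusted p = 0.271 with an estimated correlation). The p53 list had 7 up and 1 down of 22, and over the list alone 8 up and 2 down. Cdkn1a, at 72.4 ± 17.3 CPM, was up by 0.99 ± 0.15 (edgeR adjusted p = 2.68e-05) and Gdf15 by 2.21 ± 0.41 (0.000374). For p53 genes the camera adjusted p was 0.00292, and adjusted p = 0.128 with an estimated correlation. MAPK output had 4 of 14 up (2 with total counts), with Etv4 at 1.54 (edgeR adjusted p = 0.00224) and Areg at 1.31 (0.00750). Camera placed the MAPK output list up (adjusted p = 0.00239, and adjusted p = 0.128 with an estimated correlation). Checkpoint genes had 5 of 15 up, 8 over the list alone, such as Tnfrsf9, a costimulatory receptor, at 1.37 (edgeR adjusted p = 0.0101, and 0.0529 without the Myh6-high lungs). The checkpoint list had a camera adjusted p of 0.00150, and adjusted p = 0.327 with an estimated correlation. The interferon response had 4 of 21 up (1 with total counts), with the antiviral gene Rsad2 at 1.70 ± 0.34 (edgeR adjusted p = 0.00105). For interferon response genes the camera adjusted p was 0.0202, and adjusted p = 0.518 with an estimated correlation. Antigen presentation had 2 of 15 up, 3 over the list alone, with H2-K1 at 1.04 (edgeR adjusted p = 0.00261). Camera placed the antigen presentation list up (adjusted p = 0.000195, and adjusted p = 0.271 with an estimated correlation). Its members H2-Aa and H2-Eb1, of separate levels by animal, were on the high side in 6 of 10 lungs, against 2 of 10 at baseline. Without them the camera adjusted p was 0.000334, and adjusted p = 0.327 with an estimated correlation, but other H2 genes stayed in the list.

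Of 17 B and plasma cell genes 3 rose at 7 months, 6 over the list alone, with Pax5, a B cell transcription factor, at 1.03 (edgeR adjusted p = 0.0125). The B and plasma cell list had a camera adjusted p of 0.000289, and adjusted p = 0.388 with an estimated correlation. Each of the 4 erythroid genes rose, with Alas2, the erythroid enzyme of heme synthesis, from 26.2 to 110 ± 87.6 CPM (2.07, edgeR adjusted p = 0.00127). For erythroid genes the camera adjusted p was 0.000107, and adjusted p = 0.128 with an estimated correlation. Of 11 cardiac and skeletal muscle genes 4 fell, 6 over the list alone (median -1.49, camera adjusted p = 0.0202, and adjusted p = 0.518 with an estimated correlation). These markers varied widely between libraries, with Myh6 at 1211 CPM in baseline replicate 1, 587 in baseline replicate 2, 394 in baseline replicate 9, 318 in end-of-exposure replicate 1 and 610 in 3-month replicate 6. Without baseline replicate 1 the calls of the muscle genes Sbk3 (-2.72; -1.87, edgeR adjusted p = 0.0646) and Art1 (-2.57; -1.75, 0.0791) were lost. Ucp1, at -4.29 (edgeR adjusted p = 0.0223), turned to 0.61 (0.688) without that library, to 0.58 (0.761) without the 5 lungs over 300 CPM of Myh6, and to 0.59 by DESeq2 (adjusted p = 0.681). Spp1, at 128 CPM, rose by 3.16 ± 0.60 (edgeR adjusted p = 0.000660), Cd177 by 3.36 (0.000497) and Tmem2 by 3.19 (0.00911), while Asgr1 fell by 2.38 ± 0.47 (0.000889) and Lypd2 by 2.32 ± 0.44 (0.000519). Tmem2 went from 3.97 to 107 CPM in animals with the letter F and from 8.20 to 3.12 CPM in those with M. EdgeR called 1912 genes, 1121 up and 791 down, of which 418 and 235 by at least 2-fold, against 1160 without those 5 lungs and 1215 with only the 2 groups in the fit. With total counts 753 rose and 730 fell, and with limma-voom 860 rose and 1045 fell, so that the larger side depends on the method. Without 7-month replicate 9, 1188 genes were called. Of the lists 16 passed camera, 12 up and 4 down, and 0 with an estimated correlation.

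**Figure D3:**
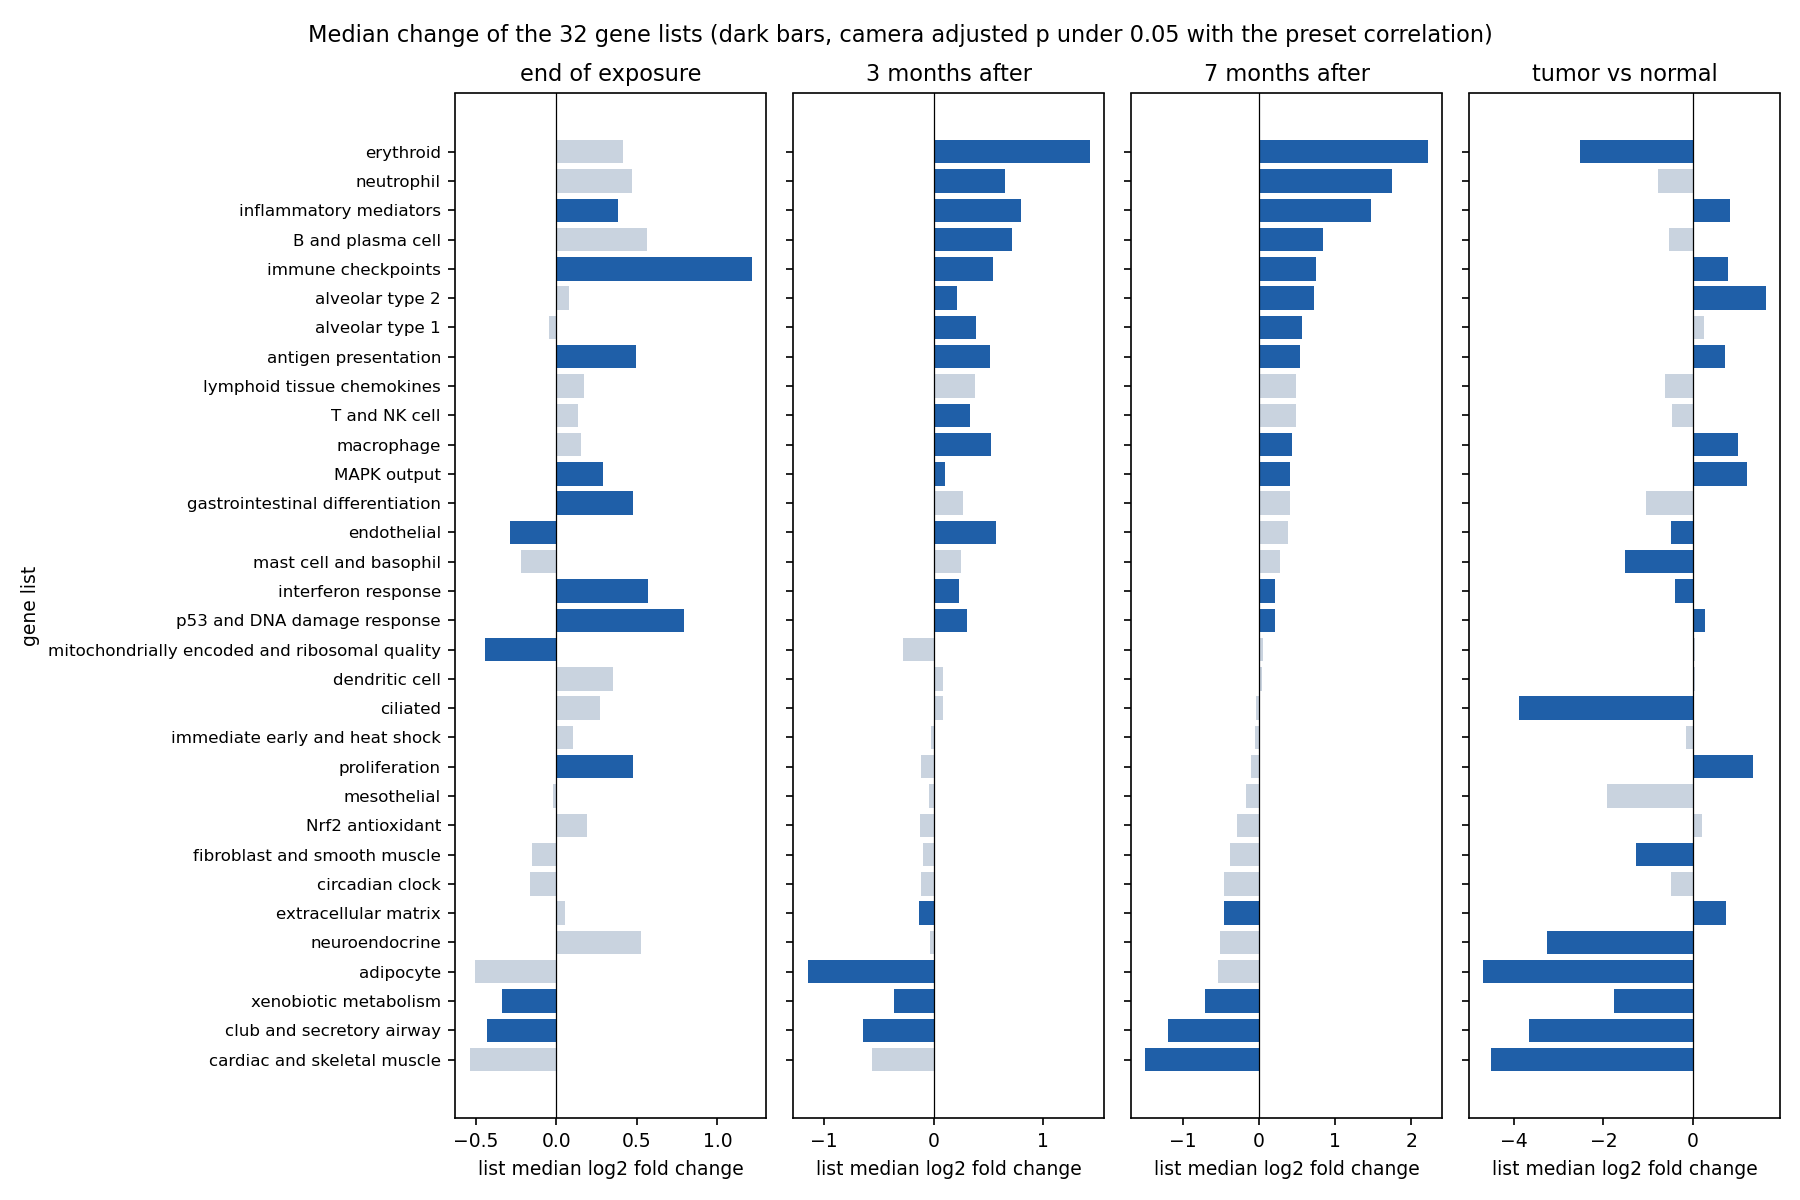
Median log2 fold change of each of the 32 gene lists against baseline at end of exposure, 3 months and 7 months in normal-appearing lung, and in tumors against matched normal lung, with dark bars where the camera adjusted p was under 0.05 and a separate axis range in each panel. Immune checkpoints were the largest rise at end of exposure with a median of 1.21, and ciliated genes fell to a median of -3.88 in tumors.

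Several lists did not pass camera at the time named. Clock genes had 3 up and 3 down of 15 at 7 months (camera adjusted p = 0.120). Npas2, an activator of the clock, rose by 2.12 ± 0.48 (edgeR adjusted p = 0.00324), with means of 11.7 CPM in animals with the letter F and 93.7 CPM in those with M, and Per3, a repressor, fell by 1.17 (0.00102). Fibroblast and smooth muscle genes had 2 up and 4 down of 17 at 7 months (camera adjusted p = 0.0791), and proliferation genes 1 down of 24 (0.141). The Nrf2 antioxidant list had 3 of 13 up at end of exposure (camera adjusted p = 0.0638), lymphoid tissue chemokines 1 of 5 up (0.366). Neuroendocrine markers had 1 of 8 up at that time (camera adjusted p = 0.0610) and adipocyte markers 1 of 8 down (0.119). At end of exposure no call by edgeR or DESeq2 was made among ciliated (camera adjusted p = 0.0604), dendritic cell (0.142), mast cell and basophil (0.691), mesothelial (0.850) or immediate early and heat shock genes (0.959), with 1, 4, 0, 1 and 3 members under an unadjusted p of 0.05.

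From end of exposure to 3 months, p53 and proliferation genes went down. Cdkn1a fell by 0.76 ± 0.15 (edgeR adjusted p = 0.00727), Gdf15 by 2.71 ± 0.41 (0.000236) and Tnfrsf10b by 0.96 ± 0.14 (0.000194). Of 22 p53 list members 7 fell, 12 over the list alone (median -0.46, camera adjusted p = 8.25e-15, and adjusted p = 1.46e-05 with an estimated correlation). Of 24 proliferation genes 4 fell, 12 over the list alone, such as Cdk1 by 1.03 ± 0.20 (edgeR adjusted p = 0.00685) and Top2a by 0.99 (0.0122). Camera placed the proliferation list down (adjusted p = 4.33e-12, median -0.52, and adjusted p = 0.0923 with an estimated correlation). Elk3, of separate levels, rose by 3.69 (edgeR adjusted p = 0.00828) and Glp1r by 1.90 ± 0.40 (0.0122). H2-Q1, not compared with H2-Aa, fell by 1.82 (edgeR adjusted p = 0.00828). The endothelial list was up with a median of 0.92 (1 of 18 called, 11 over the list alone, camera adjusted p = 8.45e-11, and adjusted p = 0.336 with an estimated correlation). EdgeR called 151 genes, 51 up and 100 down, DESeq2 318 and limma-voom 240. The count was 70, 72, 81 and 260 without 3-month replicate 2, 3, 5 and 9, and 241, 99 and 100 without end-of-exposure replicate 2, 3 and 10.

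From 3 to 7 months edgeR called few single genes. It called 8, 5 up and 3 down (2 up and 5 down when scaled by total counts, 5 up and 9 down by limma-voom), with 1975 genes under an unadjusted p of 0.05 and 104 called by DESeq2. Cth, an enzyme of cysteine synthesis, rose by 1.11 ± 0.20 (edgeR adjusted p = 0.0157) and lost its call without 7-month replicate 8 (1.02, adjusted p = 0.0616) and with only the 2 groups in the fit (1.12, adjusted p = 0.174). By camera, alveolar type 2 genes (median 0.51, adjusted p = 0.000226), neutrophil genes (0.97, 0.000226) and inflammatory mediators (0.68, 0.00477) were up, each with adjusted p = 0.754 with an estimated correlation. Muscle (-1.15, adjusted p = 0.00287), xenobiotic metabolism (-0.26, 0.00639) and matrix genes (-0.26, 0.00644) were down, with adjusted p = 0.754, 0.754 and 0.812 with an estimated correlation. The count ran from 1 to 90 as single libraries were left out. It was 3, 3 and 5 without baseline replicate 2, 4 and 6, and 5, 4 and 5 without end-of-exposure replicate 4, 8 and 10. It was 3, 5, 2, 5, 13, 3 and 13 without 3-month replicate 1, 2, 3, 4, 6, 7 and 9, and 13, 90, 35, 4, 3, 1, 3 and 5 without 7-month replicate 2, 3, 4, 5, 7, 8, 9 and 10. Across all 4 time groups together, edgeR found 1731 genes with any change and DESeq2 2665.

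Some genes were either well detected or nearly absent in a given animal, with no values between. Among 12254 genes with a mean of at least 3 CPM in normal lung, 25 autosomal genes had such separate levels, at least 4-fold apart. The class II antigen presentation gene H2-Aa was on its high side in 2 of 10 lungs at baseline, 3 of 10 at end of exposure, 9 of 9 at 3 months and 6 of 10 at 7 months. H2-Eb1, H2-Ob, Ppp1r18 and D17H6S56E-5 had the same counts. Lta4h, an enzyme of leukotriene synthesis, and Elk3, an ETS factor, were on the high side in 0, 1, 9 and 2 lungs at these times. Riok2, a ribosome assembly kinase, was so in 0, 1, 8 and 5, and Nfia in 9, 4, 9 and 6. In fits that take every gene alike, Riok2 thus had a log2 fold change of 8.31 ± 1.62 at 3 months (edgeR adjusted p = 0.00269) and 7.77 ± 1.60 at 7 months (0.00143). Lta4h had 6.81 ± 1.20 (edgeR adjusted p = 0.00103) and 4.75 ± 1.13 (0.00511), and Elk3 had 5.48 ± 0.81 at 3 months (0.000107). For each pair of such genes, the share of animals on the same side or on opposite sides was taken, whichever was larger. In pairs under 10 Mb apart in GRCm38, 16 in all, it had a median of 100%, against 61.5% in the 284 other pairs. Taking the larger share can only raise these values, and some of the near pairs have a gene in common, so they were not independent. Tumors took the side of the normal lung of their own animal in 818 of 825 gene and tumor pairs, or 99.15%.

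**Figure D4:**
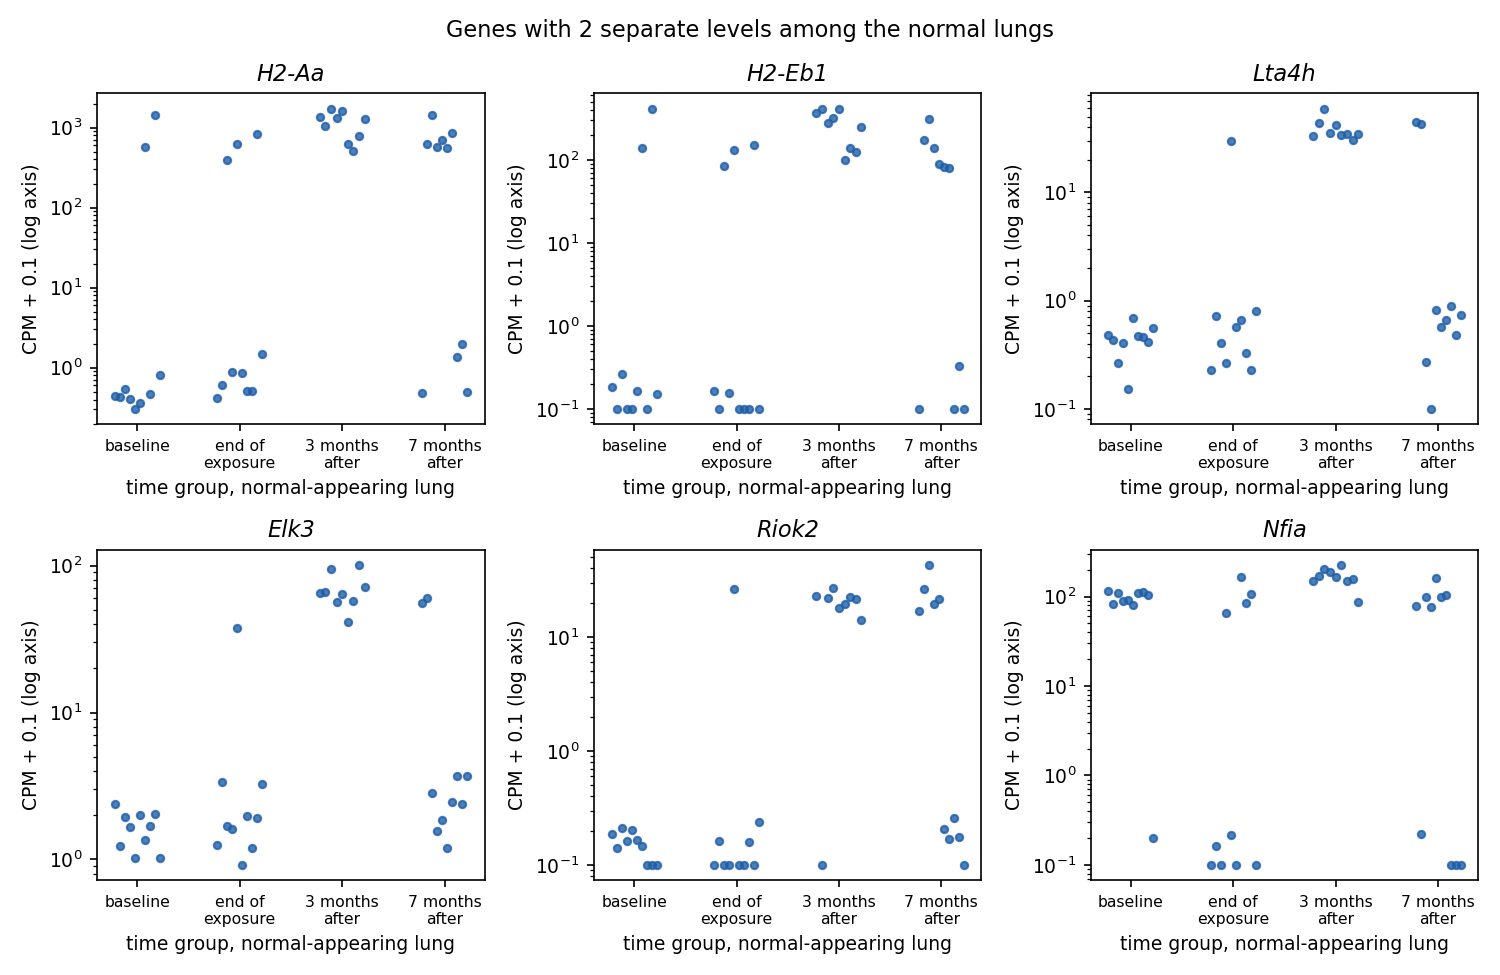
Levels of 6 genes in normal-appearing lung by time group, as CPM + 0.1 on a log axis with 1 point per library. Each gene shows a high and a low group of points, and at 3 months all 9 points of H2-Aa, H2-Eb1, Lta4h, Elk3 and Nfia lay on the high side, as did 8 of 9 of Riok2.

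Whether the change from baseline to 7 months differed between animals with the letters M and F was tested as an interaction, which called 109 genes, 62 up and 47 down. Npas2 stood at 12.9 and 11.3 CPM at baseline (F and M) and at 11.7 ± 4.78 and 93.7 ± 47.2 CPM at 7 months (n = 5 in each), an interaction of 3.20 ± 0.54 (edgeR adjusted p = 0.00602). Its partner Arntl, the central activator of the clock, had 2.58 (edgeR adjusted p = 0.0201), the clock output gene Hlf -1.96 (0.0358) and the clock repressor Nr1d2 -1.29 (0.0416). The count rested on few libraries, with DESeq2 at 511, no filter at 29 and 1244 without the 2 normal lungs of the fewest counts, 7459147 and 8940742. It was 2, 172, 4, 7, 4 and 42 without baseline replicate 1, 4, 5, 7, 9 and 10, and 13, 8, 41, 51, 944, 164, 70, 37, 9 and 21 without 7-month replicate 1 to 10 in turn.

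Tumors were compared with the normal lung of their own animal. Alveolar type 2 markers, cell cycle genes and MAPK output were higher in tumors, and airway, muscle, fat and neuroendocrine markers were lower. Lamp3, a lysosomal protein of alveolar type 2 cells, was higher in the tumors of 16 of 16 animals, with a log2 fold change of 2.82 ± 0.22 (edgeR adjusted p = 4.60e-08). Slc34a2 rose by 1.93 ± 0.20 (edgeR adjusted p = 9.56e-07) and Sftpc by 2.07 ± 0.27 (6.76e-06), to 37070 ± 25340 CPM in tumors at 7 months. Of 17 alveolar type 2 genes 14 rose, 15 over the list alone (median 1.62, camera adjusted p = 2.68e-10, and adjusted p = 0.201 with an estimated correlation). Of 15 MAPK output genes 14 rose, with Etv4 at 2.96 ± 0.25 (edgeR adjusted p = 1.19e-07), the ERK phosphatase gene Dusp6 at 1.68 ± 0.13 (4.60e-08) and its relative Dusp4 at 2.22 (2.27e-07). The MAPK output list had a median of 1.20 and a camera adjusted p of 2.68e-10, and adjusted p = 0.0331 with an estimated correlation. Of 24 proliferation genes 22 rose, 23 over the list alone, with Birc5, a gene of mitosis and survival, at 1.86 ± 0.18 (edgeR adjusted p = 3.77e-07) and Mki67 at 1.73 ± 0.26 (2.81e-05). For proliferation genes the median was 1.33 and the camera adjusted p was 1.28e-12, and adjusted p = 0.201 with an estimated correlation.

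The cell cycle inhibitor genes Cdkn2a and Cdkn1a and some p53 targets were higher in tumors as well. Cdkn2a rose by 2.44 ± 0.32 (edgeR adjusted p = 8.30e-06), Cdkn1a by 1.13 ± 0.17 (3.06e-05) and Tnfrsf10b by 1.39 ± 0.16 (1.97e-06). Of the 22 p53 list members 10 rose and 1 fell (median 0.27, camera adjusted p = 0.0251, and adjusted p = 0.201 with an estimated correlation). With total counts 7 rose and 4 fell, and the median was 0.04. Trp53 rose by 0.30 ± 0.10 (edgeR adjusted p = 0.0221), a call lost without animal 1 of the 3-month group (0.25, adjusted p = 0.0627) and with total counts (0.06, adjusted p = 0.680). Col4a1, a basement membrane collagen, rose by 2.10 ± 0.16 (edgeR adjusted p = 4.60e-08) and the elastin gene Eln by 1.55. Of 20 matrix genes 14 rose (9 with total counts), 15 over the list alone (median 0.73, camera adjusted p = 6.71e-06, and adjusted p = 0.262 with an estimated correlation). In the Nrf2 antioxidant list 5 of 13 rose and 3 fell (camera adjusted p = 0.415), and its median of 0.19 turned to -0.04 with total counts. Hmox1, heme oxygenase, rose (edgeR adjusted p = 2.60e-06) and the quinone reductase gene Nqo1 fell (0.000107).

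Lcn2 rose in tumors by 2.69 ± 0.23 (edgeR adjusted p = 1.32e-07), higher in 16 of 16 animals, and macrophage genes rose with it. Mmp12, a macrophage elastase, rose by 3.02 ± 0.22 (edgeR adjusted p = 3.43e-08) and Cd68, a lysosomal macrophage marker, by 1.56 ± 0.16 (6.96e-07). Of 18 macrophage genes 13 rose and 1 fell (median 1.01, camera adjusted p = 9.09e-05, and adjusted p = 0.201 with an estimated correlation). Of 15 antigen presentation genes 10 rose, such as H2-DMb1, a class II peptide loading gene, at 1.94 ± 0.18 (edgeR adjusted p = 2.12e-07). Camera placed the antigen presentation list up (adjusted p = 1.35e-05, and adjusted p = 0.201 with an estimated correlation). Of 15 checkpoint genes 8 rose and 1 fell. Cd276, a ligand of the B7 family, rose by 1.82 ± 0.17 (edgeR adjusted p = 3.15e-07), Cd274, the ligand of the programmed death receptor, by 0.93 ± 0.20 (0.000891) and Pdcd1 by 1.06 ± 0.35 (0.0172). Vtcn1, another B7 ligand, fell by 2.99 ± 0.65 (edgeR adjusted p = 0.000843). The checkpoint list had a camera adjusted p of 0.0124, and adjusted p = 0.458 with an estimated correlation. With total counts Pdcd1 was no longer called (0.83, adjusted p = 0.0590). Ctla4 stood at 0.56 ± 0.37 (edgeR adjusted p = 0.216). Of 20 inflammatory mediators 10 rose and 1 fell, with Cxcl3, a neutrophil attractant, at 2.81 (edgeR adjusted p = 5.49e-06; camera adjusted p = 0.00258, and adjusted p = 0.274 with an estimated correlation). In contrast, 9 of 21 interferon response genes fell (14 with total counts), with Usp18, a regulator of interferon signaling, at -1.69 ± 0.19 (edgeR adjusted p = 1.49e-06). Camera placed the interferon response list down (adjusted p = 0.0302, and adjusted p = 0.458 with an estimated correlation).

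Erythroid and mast cell markers were lower in tumors, while the neutrophil, T and NK cell, B and plasma cell, lymphoid chemokine and dendritic cell lists did not pass camera. Erythroid genes fell in 4 of 4, with Alas2 at -2.63 (edgeR adjusted p = 1.05e-05; camera adjusted p = 0.00157, and adjusted p = 0.201 with an estimated correlation). Mast cell and basophil genes fell in 7 of 9, 8 over the list alone (camera adjusted p = 0.00627, and adjusted p = 0.201 with an estimated correlation). Neutrophil genes had 2 up and 5 down of 12, with S100a9 at -1.20 (edgeR adjusted p = 0.000670; camera adjusted p = 0.153), and 0 up and 7 down with total counts. T and NK cell genes had 5 down of 21, with the granzyme gene Gzma at -1.67 (edgeR adjusted p = 1.75e-05; camera adjusted p = 0.150), and B and plasma cell genes 5 down of 17 (8 with total counts, camera adjusted p = 0.205). Lymphoid tissue chemokines had 2 of 5 down (camera adjusted p = 0.415) and dendritic cell genes 3 up and 2 down of 10, with the chemokine Ccl17 at 1.49 (edgeR adjusted p = 0.000129; camera adjusted p = 0.559).

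Airway genes fell in tumors. Of 17 ciliated genes 17 fell, with Dnah11, an axonemal dynein, at -3.80 ± 0.40 (edgeR adjusted p = 1.03e-06) and Tppp3, a microtubule protein, at -2.34 ± 0.27 (2.46e-06). For ciliated genes the median was -3.88 and the camera adjusted p was 5.37e-11, and adjusted p = 0.201 with an estimated correlation. Of 15 club and secretory airway genes 15 fell, with Cyp2f2 at -2.90 ± 0.46 (edgeR adjusted p = 4.65e-05), Cyp2a5, a P450 that activates NNK, at -5.33 ± 0.73 (1.52e-05) and Scgb1a1 at -2.67 ± 0.81 (0.0102), though higher in the tumors of 3 of 16 animals. Camera placed the club and secretory airway list down (adjusted p = 3.18e-08, median -3.66, and adjusted p = 0.201 with an estimated correlation). Muscle genes fell in 11 of 11 (camera adjusted p = 5.30e-08, and adjusted p = 0.201 with an estimated correlation), with Nppa, the atrial natriuretic peptide, at -6.75 ± 0.90 (edgeR adjusted p = 1.49e-05). Adipocyte genes fell in 7 of 8 (median -4.68, camera adjusted p = 0.00188, and adjusted p = 0.283 with an estimated correlation). Neuroendocrine genes fell in 8 of 8, such as Calca, the calcitonin gene, at -3.57 ± 0.60 (edgeR adjusted p = 8.21e-05; camera adjusted p = 0.000105, and adjusted p = 0.201 with an estimated correlation). Mesothelial genes fell in 6 of 7 (camera adjusted p = 0.0530). Among 39 normal lungs these markers went up and down together, with a median Pearson correlation between members, time and letter means removed, of 0.622 for muscle (Spearman 0.545, 0.547 without the 2 farthest libraries), 0.933 for adipocyte (0.933, 0.929) and 0.683 for ciliated (0.683, 0.651) genes. It was 0.409 for club (0.394, 0.385) and 0.596 for neuroendocrine genes (0.632, 0.534). Of the tumors, 3-month replicate 2 and 7-month replicate 22 stood apart with Foxj1, the regulator of ciliated cells, at 226 and 269 CPM.

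**Figure D5:**
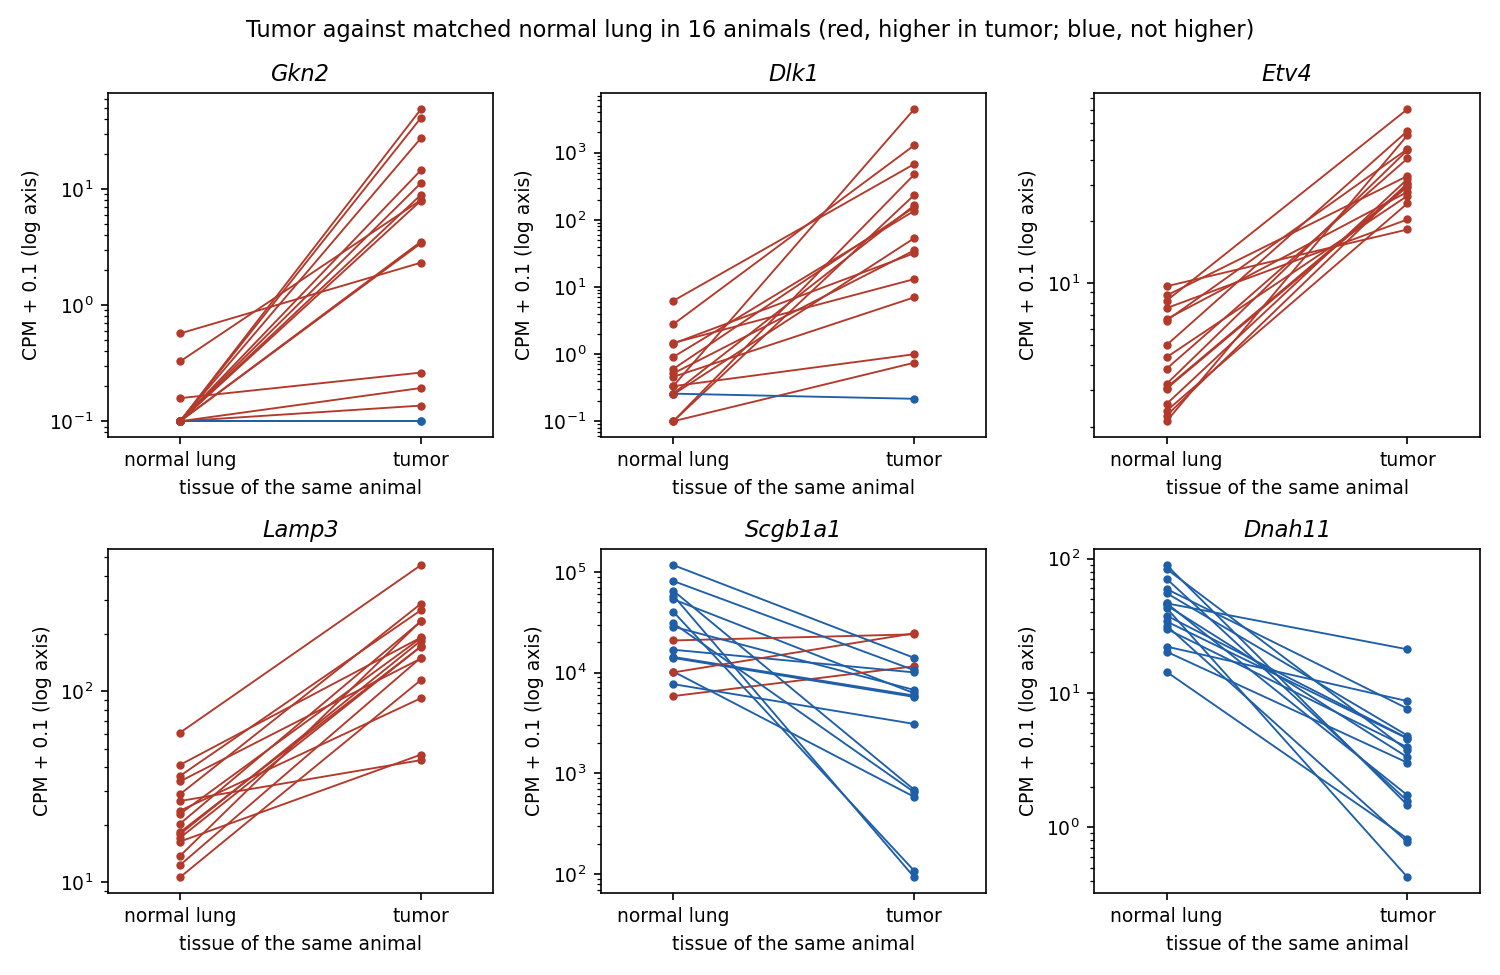
Levels of 6 genes in normal lung and tumors of the same animal, as CPM + 0.1 on a log axis, with 1 line per animal, red where the tumor mean was higher. Etv4 went from 2.02 to 9.55 CPM in normal lungs to 18.1 to 70.3 CPM in tumors and was higher in 16 of 16 animals, while Dnah11 was higher in 0 of 16 and Scgb1a1 in 3.

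Other lists in tumors were mixed. Of 22 xenobiotic metabolism genes 19 fell and 1 rose, with Aldh1a1, a retinal dehydrogenase, at -3.19 ± 0.40 (edgeR adjusted p = 4.60e-06). For xenobiotic metabolism genes the median was -1.77 and the camera adjusted p was 7.76e-09, and adjusted p = 0.201 with an estimated correlation. Of 17 fibroblast and smooth muscle genes 14 fell and 1 rose (camera adjusted p = 1.16e-05, and adjusted p = 0.201 with an estimated correlation). Of 18 endothelial genes 10 fell and 1 rose, with Vwf at -1.53 (edgeR adjusted p = 3.89e-06) and Emcn, a sialomucin of capillaries and veins, up (5.65e-06). Camera placed the endothelial list down (adjusted p = 0.0318, and adjusted p = 0.516 with an estimated correlation). Alveolar type 1 genes had 7 up and 3 down of 14, with the water channel gene Aqp5 at 1.66 (edgeR adjusted p = 3.43e-06) and Igfbp2 down (0.00117; camera adjusted p = 0.222), and 4 up and 4 down with total counts. Clock genes had 3 up and 8 down of 15 (camera adjusted p = 0.268), gastrointestinal genes 3 up and 6 down of 11 (0.352) and immediate early and heat shock genes 2 up and 1 down of 16 (0.962). With total counts these last 2 lists had 1 up and 6 down, and 2 up and 4 down. Of the 3 tested members for mitochondrially encoded and ribosomal quality edgeR called 0, as did DESeq2, with 0 under an unadjusted p of 0.05 (camera adjusted p = 0.833).

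The largest rises in tumors were in genes barely present in normal lung. Gkn2, a stomach mucosal protein, stood at 0 to 0.471 CPM in normal lungs and 0 to 48.9 CPM in tumors of the 16 animals. It was higher in the tumors of 14 (log2 fold change 7.48 ± 0.78, edgeR adjusted p = 1.44e-06). Dlk1, an imprinted Notch pathway gene of the fetus, was higher in 15 of 16 animals (7.45 ± 0.91, edgeR adjusted p = 4.99e-06). Ereg, another epidermal growth factor receptor ligand, rose by 4.96 ± 0.58 (edgeR adjusted p = 3.39e-06) and Tnfsf9, a costimulatory ligand, by 4.35 ± 0.31 (3.43e-08). The defensin-like gene Spag11b rose by 5.81 ± 0.45 (edgeR adjusted p = 4.60e-08) and Tmem213 by 4.21 ± 0.41 (5.54e-07). Among the largest falls were Hamp, the iron hormone hepcidin, at -7.71 ± 1.01 (edgeR adjusted p = 9.72e-06), and the fat genes Cfd at -7.94 ± 1.35 (0.000106) and Car3 at -7.36 ± 1.29 (0.000135). EdgeR called 7676 of 15457 genes, 3756 up and 3920 down, of which 912 and 2339 by at least 2-fold. With total counts the split was 2050 up and 5477 down, the median of all genes shifting to -0.24, so that counts of small rises and falls depend on the scaling. Of the lists 20 passed camera, 9 up and 11 down, and 1 with an estimated correlation.

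In each time group the tumor effect was also tested alone. At 7 months, with 9 animals, Lamp3 rose by 3.02 ± 0.26 (edgeR adjusted p = 2.35e-06), Dusp6 by 1.72 (9.47e-06) and Lcn2 by 2.30 (1.88e-05). Gdf15 rose by 1.75 (edgeR adjusted p = 3.64e-05) and Cdkn1a by 1.48 (7.49e-05), and the signaling gene Wnt2 fell by 3.32. EdgeR called 5843 genes there, 2785 up and 3058 down (1434 and 4341 with total counts). At 3 months, with 4 animals, Lcn2 rose by 3.51 ± 0.41 (edgeR adjusted p = 0.000375), Etv4 by 3.42 (0.000518), Lamp3 by 3.05 (0.000501) and Gdf15 by 1.83 (0.00253). EdgeR called 3046 genes, 1472 up and 1574 down (673 and 2748 with total counts). That count was 1413, 793 and 874 without animals 1, 3 and 8 of the group. At end of exposure, with 3 animals, 713 genes were called, 304 up and 409 down (199 and 448 with total counts). Among them were Etv4, at 43.0 CPM in these tumors (edgeR adjusted p = 0.0152), Mmp12 at 3.27 (0.0152) and Lcn2 at 2.74 (0.0172). Most of those early calls were lost with 2 pairs, as edgeR called 50, 4 and 0 genes without animals 2, 9 and 10. Etv4 was not called without animal 9 (3.40, adjusted p = 0.0627) or 10 (3.60, adjusted p = 0.143). Nor was Mmp12 (3.24 and 2.93, adjusted p = 0.0642 and 0.181) or Lcn2 (2.06 and 2.73, adjusted p = 0.0917 and 0.181). The end-of-exposure count was 1940 by DESeq2, 375 with no filter and 1117 without the 2 tumors over 200 CPM of Foxj1.

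Whether the tumor effect at 7 months differed from that at the 2 earlier times was tested directly. EdgeR called 0 genes, with 829 under an unadjusted p of 0.05, and DESeq2 called 0; for Gdf15 the difference was 1.19 ± 0.33 (smallest adjusted p of any gene 0.886). By camera, matrix genes were lower in the later tumor effect (median -0.61, adjusted p = 4.03e-08), as were mesothelial (-1.64, 6.74e-05), inflammatory (-0.70, 0.000206) and neutrophil genes (-0.89, 0.000318), each with adjusted p = 0.305 with an estimated correlation. Proliferation genes were lower too (-0.34, camera adjusted p = 0.000206), with adjusted p = 0.494 with an estimated correlation. Muscle genes were higher (1.39, camera adjusted p = 0.000206, and adjusted p = 0.339 with an estimated correlation), as were alveolar type 2 genes (0.45, 0.00216, and adjusted p = 0.494 with an estimated correlation). In the 2 animals with tumors of both titles, ADC against ADN gave 0 of 14000 genes by edgeR, 182 under an unadjusted p of 0.05 and 5 by DESeq2. EdgeR called 1 without tumor replicate 20 at 7 months.

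The changes of normal-appearing lung at 7 months were compared with those of tumors from the 7 animals of the earlier times, which share no library. Of 14652 genes tested in both, 1107 rose and 776 fell in the lung and 2233 rose and 2323 fell in tumors. Both rose in 310 genes, against 168.7 from the products of the counts, and both fell in 214, against 123. In opposite directions were 120 and 75 genes, against 175.5 and 118.3. Of the shared genes, 72.9% thus had the same direction, 524 against 195, and at an adjusted p of 0.01 the counts were 114 and 29, or 79.7%. Among the genes up in both, also at the stricter threshold, were Lcn2, Etv4, Marco, Gpnmb and the complement gene Hc.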

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

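Of the tests in this part, those of a haplotype, of a response to exposure or age, of scaling between tissues, of the time of day, of a letter-dependent change and of fits without the shallow libraries were chosen after the result was seen, and the others were not.

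Single libraries far from the rest of their group were looked for in 192 sets of values (32 values in 6 groups), and 46 were found. A chance rate of about 1 in 20 was assumed by the rule and was not measured on these values. The values included genes of separate levels, such as H2-Aa, and genes barely present in normal lung, such as Gkn2. The count of 46 thus does not show that such libraries were more common than chance gives. The libraries named most often were tumor replicate 3 at end of exposure with 5 values and baseline replicate 9 with 4. Values are in CPM, with the nearest other library of the group in brackets.

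In immune and inflammatory genes, end-of-exposure replicate 4 had the highest Lcn2 at 269 (120), Pdcd1 at 27.0 (14.5) and Ctla4 at 42.3 (13.9). Tumor replicate 4 at 3 months had the highest Cd274 at 116 (47.4), Pdcd1 at 72.8 (11.5) and Ctla4 at 59.2 (6.64). Cd274 also stood high in baseline replicate 9 at 47.9 (20.7) and in tumor replicate 4 at end of exposure at 93.9 (23.6), and Pdcd1 in baseline replicate 10 at 3.78 (2.14). Marco was high in 3-month replicate 5 at 19.3 (8.60), S100a9 in 3-month replicate 9 at 86.7 (42.6), and Gpnmb was low in tumor replicate 2 at end of exposure at 5.93 (25.8).

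In p53 targets, Gdf15 was high in baseline replicate 10 at 4.60 (2.48), end-of-exposure replicate 1 at 152 (53.7) and tumor replicate 3 at 3 months at 43.1 (17.7), Eda2r in tumor replicate 4 at end of exposure at 14.7 (8.14) and Phlda3 in 7-month replicate 9 at 126 (82.9). Of the MAPK output genes, Etv4 was high in baseline replicate 9 at 4.46 (2.45). Dlk1 was high in end-of-exposure replicate 8 at 2.55 (0.508), 3-month replicate 5 at 1.94 (0.807), 7-month replicate 1 at 6.12 (2.69) and tumor replicate 1 at 3 months at 4450 (271). Gkn2 was high in end-of-exposure replicate 1 at 0.0635 (0), 7-month replicate 8 at 0.471 (0.228) and tumor replicate 3 at end of exposure at 41.1 (6.64).

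Of airway and heart genes, Scgb1a1 was high in 3-month replicate 9 at 80430 (38100) and in tumor replicate 2 at 3 months at 48920 (5916), Tppp3 in 3-month replicate 7 at 2135 (1401) and in the same tumor at 1145 (217). Myh6 was high in baseline replicate 1 at 1211 (587), 3-month replicate 6 at 610 (146) and again in that tumor at 47.5 (5.70). Npas2 was high in baseline replicate 1 at 25.5 (14.6), and end-of-exposure replicate 3 had the most genes with a count, about 18640 (18020).

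Genes with separate levels gave values far from their group as well. In baseline replicate 9 these were H2-Aa at 1417 (571) and H2-Eb1 at 412 (140), and in baseline replicate 10 Nfia at 0.102 (79.6). In end-of-exposure replicate 5 they were Lta4h at 29.8 (0.697), Elk3 at 37.5 (3.26) and Riok2 at 26.2 (0.139). Tumor replicate 3 at end of exposure had H2-Aa at 1639 (1.11), H2-Eb1 at 557 (0), Nfia at 151 (0) and Riok2 at 0.286 (0). At 3 months Lta4h was high in replicate 3 at 59.4 (43.4) and Riok2 was at 0 in replicate 2 (14.1).

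The separate levels of H2-Aa, Lta4h, Riok2 and 22 other genes were weighed first. A response to exposure or age shared by all animals of a time was argued against. By 35.11 percentage points, tumors took the side of their own animal's normal lung more often than that of other animals of the time. A response in some animals only would give the same match, and was not tested. In some genes the sides also went with time, such as Lta4h, high in 0 of 10 lungs at baseline and 9 of 9 at 3 months. Library depth was argued against too, as the total counts of low-side over high-side animals had a median ratio of 0.943. A variant or haplotype that differs between animals stayed open: tumors took the side of their own animal in 99.15% of cases, and most genes under 10 Mb apart divided the animals alike. The data are consistent with an amplicon that fails on 1 haplotype, but litters, lines and genotypes stand in no label used here.

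The fall of heart, fat, airway and neuroendocrine markers in tumors was weighed next. For scaling between tissues, the 5 list medians with total counts, relative to the median of all genes, were still at -3.24 or lower. A change of scaling moves all genes by about the same amount, so this relative value could hardly have changed and does not decide on scaling. With nothing subtracted, the 5 medians with total counts were at -3.48 or lower, against -0.24 for all genes. Cells of heart, fat and airway that were caught in the normal samples and not in the tumors stayed open, as members of each list of muscle, adipocyte, club and ciliated markers went together across normal lungs with a median correlation of at least 0.409, against at most 0.165 in 1000 random lists. A loss of such cells or of their expression inside tumors could give the same fall, and was not tested.

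Clock genes were weighed last, within the interaction of animal letter and time that called 109 genes. Its members named by the rule were Nppa at 9.62 (6.68, adjusted p = 0.139, without baseline replicate 1, where the interaction called 2 genes), Cntnap2 at 5.47, Armcx1 at 5.12, Npas2 at 3.20, H2-T22 at -9.64, Tmem2 at -6.13, H2-DMb2 at -4.57 and Npy1r at -3.37. Some of these genes varied widely within groups of 5 animals. H2-T22 ran from 0.102 to 39.2 CPM in M at baseline and from 0.143 to 133 CPM in F at 7 months. H2-DMb2 ran from 2.45 to 24.3 and from 3.87 to 43.3 CPM in the same groups, and Tmem2 from 2.30 to 30.1 CPM in M at baseline. Whether such levels go by animal, as in the genes of separate levels, was not tested. Library depth was argued against for Npas2, whose difference was 3.47 without the 2 shallow libraries. A different time of day at collection stayed open, with 14 of 15 clock genes going the way of a shift in phase. It cannot be told apart from a letter-dependent change after exposure, since the clock score differed by 2.12 between M and F at 7 months and the labels used here hold no collection time.

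Other splits of the same libraries were counted for each comparison, and the counts of splits include the real grouping. The counts argued against chance at end of exposure (612 genes, at most 140 in other splits) and at 3 months (257, at most 2). At 7 months (1912) 2 of 100 splits gave as many, the real one among them. The other gave 2046 and kept 16 of 20 lungs in their group, so such a count was rare, but chance was not excluded. The counts also argued against chance from end of exposure to 3 months (151, at most 4) and for any change over time (1731, at most 125). For tumors they argued against it over all times (7676, at most 5405, in a split that turned 1 of 16 pairs) and at 7 months (5843, at most 0 by edgeR). For the tumors at end of exposure (713, at most 0) and at 3 months (3046, at most 0) the splits, 4 and 8, were too few. From 3 to 7 months 5 of 100 splits gave at least the 8 genes, the real one among them, and 1 gave 1981. For the letter by time interaction 5 of 100, again with the real one, gave at least 109 and 1 gave 1231. In these 2 comparisons chance could not be excluded, and whether the samples hold a structure other than the groups was not tested. For the difference of the tumor effect edgeR called 0 genes, so each of the 24 splits had to give as many (at most 1), and this count says nothing about chance.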

How the results depend on the processing

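Fits without lungs over 300 CPM of Myh6, without the 2 shallow lungs, without tumors over 200 CPM of Foxj1 and most fits that left out 1 library or animal were chosen after the results were seen. Of 964 values of 108 named genes in comparisons, 897 counted as the same, 58 lost and 7 gained the call and 2 turned. A turn of sign was counted only where the gene was called in the main fit or in the other. Turns of genes called in neither fit, and called genes without an adjusted p in the other fit, counted as the same. Under every setting run, 77 of the 108 counted as the same. The 2 that turned were Ucp1 at 7 months, 0.59 by DESeq2 and 0.58 without Myh6-high lungs, and leaving out single libraries gave -0.797 (without replicate 5) to 5.65 for Riok2 at end of exposure and -4.87 to 0.606 (without baseline replicate 1) for Ucp1 at 7 months.

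Counts that moved by over 1.5 times were as follows, and the cause was not tested. With DESeq2 they were 433 at 3 months, 318 from end of exposure to 3 months, 104 from 3 to 7 months, 2665 for any change, 1940 in tumors at end of exposure, 511 for the interaction and 5 for ADC against ADN. With limma-voom they were 240 from end of exposure to 3 months and 14 from 3 to 7 months. With no filter they were 5 from 3 to 7 months, 375 in tumors at end of exposure and 29 for the interaction. With only the groups compared they were 1063, 1215 and 1 at end of exposure, at 7 months and from 3 to 7 months. Without Myh6-high lungs they were 349 and 1160 at end of exposure and 7 months. Without the shallow lungs they were 36 from 3 to 7 months and 1244 for the interaction, and without Foxj1-high tumors 1117 at end of exposure. Shared genes of field and tumor with the same direction numbered 114 at an adjusted p of 0.01. Lists passing with an estimated correlation were 1, 1, 0 and 1 at end of exposure, 3 months, 7 months and in tumors, and with fry 5 at 3 months.

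Without a replicate block the tumor counts were 7311 over all times, 969 at end of exposure, 1221 up and 1009 down at 3 months, and 5554 at 7 months, and Ctla4 in tumors was then called at 1.21 (adjusted p = 0.0377).

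Leaving out 1 library or animal gave 431 to 677 genes at end of exposure, 175 to 287 at 3 months, 1188 to 2465 at 7 months, 70 to 260 from end of exposure to 3 months, 1 to 90 from 3 to 7 months and 1327 to 2203 for any change. It gave 7087 to 7696 in all tumors, 0 to 50, 793 to 3341 and 5082 to 5788 at the 3 times, 0 to 0 for the difference, 2 to 944 for the interaction and 0 to 1 for ADC against ADN. Of 82 called values of named genes, 18 lost the call without at least 1 library. Of list members named by the rule, 3 of 23 lost it at end of exposure, 6 of 16 at 3 months, 9 of 62 at 7 months, 8 of 18 from end of exposure to 3 months and 5 of 5 from 3 to 7 months. In tumors 0 of 109 lost it over all times, 46 of 46 at end of exposure, 30 of 79 at 3 months and 4 of 111 at 7 months, and for the interaction 7 of 8. Cd274 at 7 months was called without baseline replicate 9 (1.11, adjusted p = 0.00466) and Mki67 without 7-month replicate 3 (-0.68, adjusted p = 0.0447). In the tumors at end of exposure, with 3 animals, the self-test found 3 of 100 changes of 2-fold, so few changes of that size could be called there. What depth alone limits was not tested.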

Other observations

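No test in this part was chosen beforehand, and the values are given as measured.

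Some genes outside the lists also stood out. Among those up both in the lung at 7 months and in the earlier tumors were Atp6v0a4, Atp6v0d2, the anion exchanger Slc26a4, the chitinase-like Chil1 and the lipid enzyme Scd1. At end of exposure, single tumors carried genes nearly absent from the others: Cst6, a cystatin, ranged from 0.0714 to 508 CPM and Moxd1, a monooxygenase-like gene, from 0.129 to 259 CPM over 4 tumors. Dlk1 ranged from 0.116 to 4450 CPM in the tumor means of 16 animals.

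Of the 7 gene and tumor pairs in which a gene with separate levels was not on the side of the normal lung of the same animal, 3 were in a single tumor, replicate 6 at 7 months. It had Lta4h at 11.3 CPM against 0.172 in the normal lung and Tmtc3 at 4.39 against 0, and Elk3 was also high. The others were Trim12a in 3 tumors at 7 months (replicates 3, 5 and 11) and Clasrp in tumor replicate 6 at 3 months. The score of clock genes differed between M and F by 0.0269 at baseline, -0.416 at end of exposure, 1.35 at 3 months and 2.12 at 7 months, where the highest F animal stood at -2.32 and the lowest M animal at -0.741. Cry1 was the 1 of 15 clock genes to go the other way.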
